A study of Danio rerio with 12 samples.

How the data were processed

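Whole zebrafish embryos, wild type per the labels, were exposed to 0, 6, 30 or 50 µg/L methylmercury from 4 to 72 h post-fertilisation, with 3 samples per group and 12 samples in all. Per the labels' protocols, RNA was taken with TRIzol, poly(A) RNA was isolated on oligo(dT) beads, fragmented and copied with random primers, and the libraries were sequenced as paired reads of 150 bases.

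The deposited table holds 32057 Ensembl genes with a raw count and an FPKM value for each of the 12 libraries. The deposited counts are whole numbers of reads per gene, with no normalization, and the submitters' processing notes name FastQC 0.10.1, cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1 and DESeq2 and the build GRCz11, without saying which step each served. The annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty. The same holds for near-identical copies such as the green opsin, ferritin-like, chemokine, class I and trypsin genes. The deposited FPKM values equal the count divided by the exonic gene size and the library's summed counts, within 0.005 for 100% of values in every library. Gene symbols and coordinates are those of the deposited table. All columns of values were mapped to samples by the codes in the sample titles.

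The planned test assumed FPKM only, with the edgeR test as the main test should raw counts be present. As counts were present, edgeR 4.0.16 in R 4.3.3 was used on them (TMM scaling, quasi-likelihood fit, two-sided tests, Benjamini-Hochberg adjustment within each comparison, adjusted p under 0.05). Limma 3.58.1 with a trend on log2(FPKM + 1) became an alternative. Genes with a mean FPKM over the 12 libraries of at least 0.5 were tested, 19821 in all. The 12 libraries were fitted together with 4 groups and no other covariate, so that all groups shared the estimate of spread, and the dose trend used the concentration in µg/L as a number. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic, which is approximate. The counts called at all 3 doses are the intersection of the 3 comparisons with the control. Unchanged groups were also simulated against shared controls. There every library, controls included, was redrawn around the control mean, each gene independently, with separate spreads for control and exposed libraries. Shifts common to many genes of a library were not simulated.

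Gene lists for tissues and stress responses, 48 in all, were fixed before the data were examined. Of 1248 symbols on them, 1197 matched the table, 15 matched through reference tables of symbols and 36 did not match. Each list was tested with camera from limma at a preset correlation of 0.01 between genes, adjusted over the lists, with an estimated correlation and fry as alternatives. Calls at the estimated correlation held for 3 lists at 6 µg/L (photoreceptor, exocrine pancreas and intestine), for 2 at 30 µg/L (photoreceptor and cell cycle) and for 1 at 50 µg/L (photoreceptor). They held for 0 lists at 30 against 6 µg/L and for 1, the photoreceptor list, at 50 against 30 µg/L.

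The genes named were chosen by a rule fixed before the data were examined. For each dose against control and for the dose trend, it took the 10 largest rises and the 10 largest falls among genes past the threshold that had a symbol and whose 3 exposed libraries all lay on the same side of the 3 controls. For each list described it took up to 4 members with the smallest p, and for genes called at all 3 doses the 10 whose largest p was smallest. The genes mt2, gstp1, gclc, hmox1a, txnrd3, prdx1, hsp70.3, mmp9 and cdkn1a were reported whatever their result. Only part of the genes so chosen are printed. Not all genes and gene lists that were tested are reported here.

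Library totals ran from 15665053 to 22207603 counts. A group with no count for a gene was given a floor of 3 counts over its 3 libraries, which covers counting error only, as reads were not marked by molecule. In simulated data modelled on the comparison of 50 µg/L with control, with 19333 genes tested, edgeR recovered 63 of 100 genes changed 2-fold and 97 of 100 changed 4-fold, and 5 of its 165 calls were false. DESeq2 1.42.0 recovered 73 and 99, and 27 of its 199 calls were false. The simulation gave all libraries the same spread per gene and drew genes independently. The real controls spread more than the exposed groups, so these rates need not hold for the real comparison.

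Alternatives chosen before the data were examined were a pseudocount of 0.1 with limma, no expression filter, a minimum mean FPKM of 2, median-of-ratios scaling, quantile normalization with limma and a block for the replicate number. The others so chosen were an absolute log2 fold change of at least 1, an adjusted p under 0.01, a fit on the compared groups only, robust estimation, dose as a rank, leaving out each library in turn, the estimated correlation and fry. Alternatives chosen after seeing the data were DESeq2, library totals as the only scaling, a length correction (a smooth trend of each library on exonic length, as an offset), control replicate 3 as the only control, and limma on log2(FPKM + 1). With scaling by library totals only the median change of all genes was -0.13 (log2) at 30 against 6 µg/L. With limma on log2(FPKM + 0.1) it was 0.12 at 6 µg/L and -0.13 at 30 against 6 µg/L, so directions of small changes there are relative to that shift. No genome sequence was used here, so GC content was not examined. Figures were drawn with matplotlib 3.10.9.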

Results

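Wild-type zebrafish embryos were held from 4 to 72 h post-fertilisation in 0, 6, 30 or 50 µg/L methylmercury (MeHg), an organic mercury compound that enters the nervous system, and poly(A) RNA from whole embryos was sequenced. The 12 libraries formed 4 groups of 3 and held 15665053 to 22207603 gene counts each. The totals were 15784965, 20928762 and 20610418 in the controls and 17150992, 20251479 and 15665053 at 6 µg/L. They were 21912354, 17952303 and 22207603 at 30 µg/L and 18593766, 17586230 and 20187568 at 50 µg/L. Levels below are CPM, gene counts relative to the scaled library total, given as mean ± SD with n = 3 per group, and changes are log2 fold changes ± SE. The series was made to find genes whose expression reports MeHg toxicity, so each dose was compared with the control, neighbouring doses with each other, and expression with dose. The labels do not say that the 3 samples of a group came from separate clutches or tanks, so p-values measure only the spread between these samples.

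The exposed groups were tight and the controls were not. The first principal component held 41.3% of the variance and ordered the groups by dose, while control replicate 3 lay apart from the other controls. Its Spearman correlation with control replicates 1 and 2 was 0.927 and 0.944, against 0.991 between those 2 libraries. In addition, 3337 genes differed at least 2-fold between it and their mean, against 424 between control replicates 1 and 2. With the libraries at 6 µg/L, control replicate 3 correlated at 0.966, 0.973 and 0.971. For control replicate 1 these values were 0.953, 0.933 and 0.938, and for control replicate 2 they were 0.966, 0.950 and 0.954. The correlations thus do not tell which of the controls are the unusual ones. The biological coefficient of variation was 0.312 in the control group and 0.103, 0.0781 and 0.0643 in the groups at 6, 30 and 50 µg/L. The libraries also differed by transcript length. The median deviation of the longest eighth of genes minus that of the shortest eighth was -0.69 and -0.53 (log2) in control replicates 1 and 2 and 0.19 in control replicate 3, and it lay between -0.09 and 0.19 in the exposed libraries. No pair of libraries was close enough to be a repeat of the same library, and all 12 were used.

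**Figure D1:**
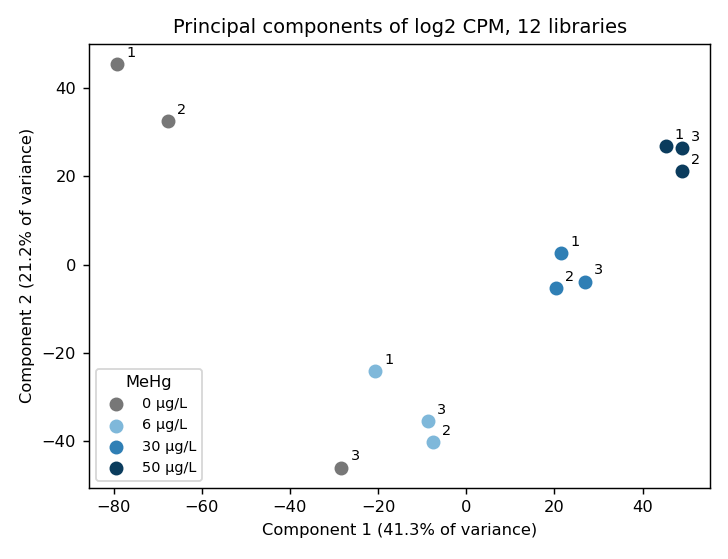
Principal components of log2 CPM over the 12 libraries, with the share of variance on each axis, colour for the dose and the replicate number beside each point. Control replicate 3 lies apart from control replicates 1 and 2, and the exposed libraries group by dose.

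At 6 µg/L the transcripts of cone photoreceptors, the light-sensing cells of the larval eye, were lower than in controls. The cone transducin subunit gene gnat2 (ENSDARG00000042529, chromosome 8, 25225590 to 25247284 in GRCz11) went from 182 ± 19.6 CPM in controls to 21.1 ± 3.83 CPM, a change of -3.10 ± 0.17 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.1e-06). Its partner gnb3b changed by -3.45 ± 0.19, the blue cone opsin opn1sw2 by -3.22 ± 0.23 and the outer segment rim protein gene prph2a by -3.14 ± 0.20. So did the cone arrestin genes arr3b and arr3a, by -3.25 ± 0.21 and -2.26 ± 0.15, and the opsin kinase genes grk1b and grk7a, by -3.50 ± 0.23 and -3.00 ± 0.20. Of 39 photoreceptor genes tested, 31 fell and none rose (32 and 0 adjusted over the list alone). Their median change was -2.26 (camera adjusted p = 1.2e-71, and adjusted p = 0.0055 with an estimated correlation). The median was -2.09 without control replicate 3 and -2.45 with that library as the only control.

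Genes of the digestive organs were lower as well. In the exocrine pancreas, which makes digestive proteases, 12 of 14 genes fell and 0 rose (13 and 0 adjusted over the list alone). The median was -2.48 (camera adjusted p = 4.8e-24, and adjusted p = 0.011 with an estimated correlation). The trypsin genes prss59.2 and prss1 changed by -3.94 ± 0.29 and -1.86 ± 0.18 and the chymotrypsinogen gene ctrb1 by -2.51 ± 0.23. In the intestine list 6 of 12 genes fell and 0 rose (7 and 1 adjusted over the list alone; median -0.99, camera adjusted p = 3.8e-05, and adjusted p = 0.022 with an estimated correlation). Among them were fabp6, which carries bile acids (-4.08 ± 0.46), the brush border peptidase gene anpepb (-1.28 ± 0.18) and tm4sf5 (-3.31 ± 0.32). The intestine call was lost when only genes with a mean FPKM of at least 2 were tested. Of 51 liver genes 12 fell and 3 rose (18 and 3 adjusted over the list alone). The median was -0.36 (camera adjusted p = 2.1e-06, but adjusted p = 0.71 with an estimated correlation). The liver fatty acid binding protein gene fabp10a (-2.52 ± 0.23), the retinol binding protein gene rbp2b (-3.59 ± 0.18), the complement gene c3a.2 (-2.54 ± 0.24) and the urate oxidase gene uox (-1.78 ± 0.17) fell. Control replicate 3 moved with the liver list, whose median was 0.28 when that library was the only control.

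Skeletal muscle and hair cell genes also lost expression. Of 53 muscle genes 18 fell and 1 rose (24 and 1 adjusted over the list alone; median -0.41, camera adjusted p = 2.1e-06, but adjusted p = 0.31 with an estimated correlation). With control replicate 3 as the only control the median was -0.085. The myosin heavy chain genes myhb and myhz1.1 changed by -1.87 ± 0.13 and -1.36 ± 0.17 and the fast troponin I gene tnni2a.1 by -2.16 ± 0.24. In the hair cell and lateral line list 6 of 17 genes fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.0027, but adjusted p = 0.071 with an estimated correlation), led by the calcium buffer gene pvalb8 (-1.32 ± 0.11) and the otolith protein gene stm (-0.74 ± 0.10). Genes of nuclear-encoded oxidative phosphorylation had 26 of 98 members lower and 0 higher (71 and 0 adjusted over the list alone). Their median was -0.48 (camera adjusted p = 1.5e-11, but adjusted p = 0.71 with an estimated correlation), and it was 0.047 with control replicate 3 as the only control.

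Inflammation genes rose at this lowest dose. The largest rises included the chemokine gene ccl20a.3 (0.131 ± 0.0816 to 1.95 ± 0.594 CPM, a change of 3.74 ± 0.53) and irg1l, an immune-responsive gene of epidermis and macrophages (14.3 ± 7.34 to 117 ± 3.49 CPM, 3.02 ± 0.29, adjusted p = 5.1e-05). Others were ms4a17a.8 (3.21 ± 0.30), the NF-kappa B cofactor gene bcl3 (2.07 ± 0.29) and the apoptosis factor gene xaf1 (2.03 ± 0.37). The level of irg1l was 18.2 ± 4.76 CPM at 30 µg/L and 16.7 ± 1.83 CPM at 50 µg/L. In the inflammation and wound response list 12 of 34 genes rose and 0 fell (18 and 2 adjusted over the list alone). The median was 0.53 (camera adjusted p = 2.2e-05, but adjusted p = 0.31 with an estimated correlation). The prostaglandin synthase gene ptgs2b rose by 1.22 ± 0.23. The largest falls outside the tissues above were in the cytochrome P450 gene cyp2aa7 (5.90 ± 0.787 to 0.127 ± 0.0384 CPM, -5.49 ± 0.28), the class I antigen presentation gene mhc1zba (-4.93 ± 0.41) and scpp5, a tooth and scale matrix gene (-4.48 ± 0.38). Both ms4a17a.8 and scpp5 belong to a set of genes, taken up below, that swung one way from 6 to 30 µg/L and back from 30 to 50 µg/L.

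The classical mercury response was small at 6 µg/L. The metallothionein gene mt2, which binds heavy metals, stood at 16.2 ± 2.14 CPM against 27.8 ± 10.4 CPM in controls (-0.78 ± 0.25, adjusted p = 0.057), and this difference passed the test in DESeq2 and without control replicate 3 (-1.07). Of 33 glutathione and Nrf2 target genes 8 rose and 4 fell (10 and 4 adjusted over the list alone), and the list did not pass (median -0.01, camera adjusted p = 0.29). Its median depended on the controls, with -0.09 without control replicate 3 and 0.33 with that library as the only control. The glutathione reductase gene gsr rose by 0.86 ± 0.11 and the glutathione transferase gene gstp2 by 1.12 ± 0.19. The transferase gstp1 rose by 1.07 ± 0.21, the peroxiredoxin prdx1 by 0.89 ± 0.20, the glutamate-cysteine ligase gclc by 0.56 ± 0.11 and the thioredoxin reductase txnrd3 by 0.34 ± 0.09. In contrast cdkn1a, a brake on the cell cycle, fell by 0.85 ± 0.18. Of 50 cell cycle genes 13 rose and 1 fell (19 and 3 adjusted over the list alone; median 0.19, camera adjusted p = 0.0031, but adjusted p = 0.66 with an estimated correlation), and the call was lost without control replicate 3. The matrix metalloproteinase gene mmp9 rose by 0.81 ± 0.24 (adjusted p = 0.045). The heat shock gene hsp70.3 (-0.14 ± 0.27) and the haem oxygenase gene hmox1a (-0.33 ± 0.30) did not pass. The calls of gstp1, prdx1, gclc, txnrd3, cdkn1a and mmp9 were lost when only the 6 libraries of the compared groups were fitted, and that of mmp9 also when any of 10 single libraries was left out.

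In all, 1086 genes were higher and 1760 lower at 6 µg/L among 19821 tested. With library totals as the only scaling the numbers were 1393 and 1362, and limma on log2(FPKM + 1) gave 1789 and 1450, so the balance of rises and falls depended on the method. Of all tested genes, 25.9% had no overlap between the 2 groups, against 10% by chance per gene. Genes of a library can shift together, so the share over all genes can depart from 10% without an effect of dose. The count rested on the spread borrowed from the other groups and on control replicate 3. Fitted on the compared groups alone it was 124 higher and 423 lower, without control replicate 3 it was 5664 and 5526, and with that library as the only control 2420 and 2497. Leaving out single libraries gave totals from 1228, without MeHg6 replicate 2, to 11190, without control replicate 3.

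**Figure D2:**
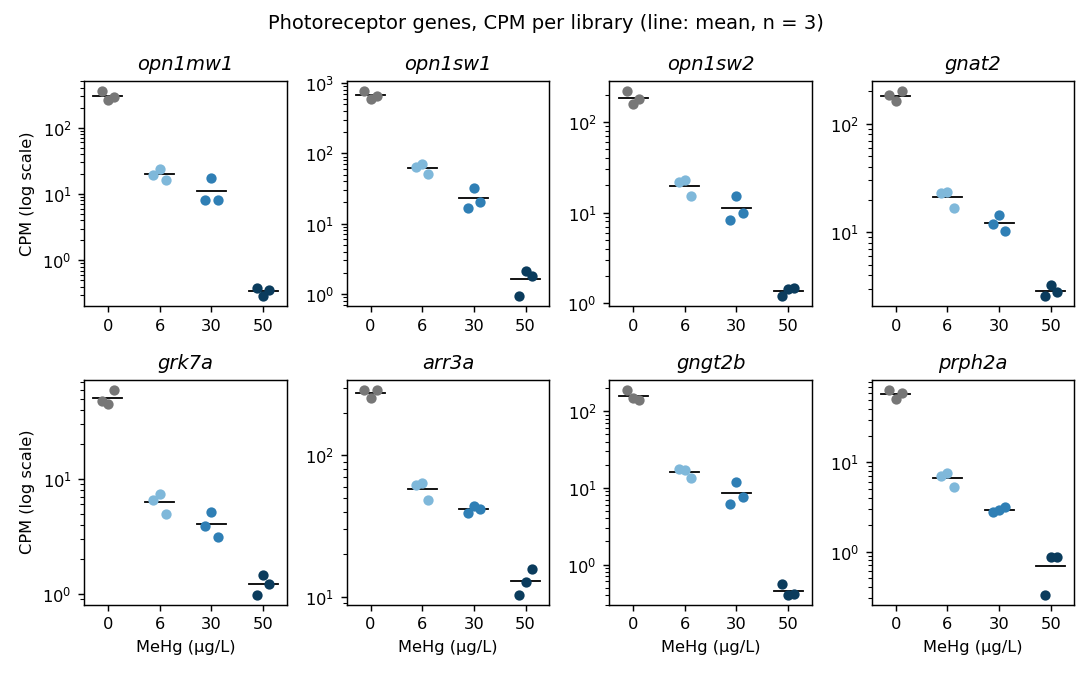
CPM of 8 photoreceptor genes on a log axis against the MeHg concentration, with 1 point per library and a line at the mean of 3. In each gene all exposed libraries lie below all control libraries.

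At 30 µg/L photoreceptor genes were lower still, and proliferation and stress genes were higher than in controls. The ultraviolet cone opsin gene opn1sw1 (chromosome 4, 13577665 to 13580348) went from 678 ± 83.0 to 22.9 ± 7.98 CPM (-4.89 ± 0.27, adjusted p = 4.9e-07) and the green cone opsin gene opn1mw1 from 305 ± 47.9 to 11.2 ± 5.36 CPM (-4.77 ± 0.29). Of the 39 photoreceptor genes 35 fell and 0 rose (36 and 0 adjusted over the list alone; median -2.86, camera adjusted p = 1.9e-73, and adjusted p = 0.0051 with an estimated correlation). Cell cycle genes went the other way: 35 of 50 rose and 0 fell (41 and 0 adjusted over the list alone). The median was 0.83 (camera adjusted p = 7.3e-27, and adjusted p = 0.047 with an estimated correlation). The topoisomerase gene top2a rose by 1.22 ± 0.09, the mitotic kinase gene plk1 by 1.03 ± 0.09 and the mitotic kinesin gene kif23 by 1.15 ± 0.09. The median of the cell cycle list was 0.75 without control replicate 3 and 1.07 with it as the only control.

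Thiol defence genes and mt2 rose. mt2 (chromosome 18, 17534627 to 17535979) reached 134 ± 28.6 CPM (2.27 ± 0.25, adjusted p = 5.5e-05). The metallothionein and zinc transport list did not pass, with 2 of 6 genes risen and 1 fallen (the same counts adjusted over the list alone; median 0.21, camera adjusted p = 0.31). Of the 33 glutathione and Nrf2 target genes 19 rose and 3 fell (19 and 3 adjusted over the list alone). The median was 0.61 (camera adjusted p = 2e-12, but adjusted p = 0.33 with an estimated correlation). Here prdx1 rose by 2.86 ± 0.21, gsr by 2.24 ± 0.12, gstp1 by 2.11 ± 0.22, gclc by 1.18 ± 0.11, txnrd3 by 0.63 ± 0.09 and the pentose phosphate enzyme gene taldo1 by 1.13 ± 0.10. The heat shock genes hsp70.3 (1.51 ± 0.27), hsp90aa1.2 (1.25 ± 0.14), hspa8b (1.66 ± 0.25) and hsp90ab1 (1.22 ± 0.19) rose. Their list had 9 of 26 higher and 1 lower (10 and 1 adjusted over the list alone; median 0.26, camera adjusted p = 0.010, but adjusted p = 0.65 with an estimated correlation). That list's call was lost without control replicate 3, where its median was 0.16. The cell cycle inhibitor gene cdkn1a rose by 1.05 ± 0.17. hmox1a did not pass (0.61 ± 0.30, adjusted p = 0.14), nor did mmp9 (0.14 ± 0.24). hmox1a passed with a length correction and without control replicate 1 (0.93), and it was at 1.86 with control replicate 3 as the only control.

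Large rises at 30 µg/L included those of ferritin-like and immune genes. The ferritin-like genes fthl29 (4.84 ± 0.71) and fthl28 (3.14 ± 0.32) lie in the same cluster on chromosome 3 and belong to a family of near copies, so the split of reads between them is uncertain. The iron handling list did not pass (3 of 15 risen and 4 fallen, 4 and 4 adjusted over the list alone; median 0.25, camera adjusted p = 0.86). The cytochrome gene cyb561a3b rose by 3.83 ± 0.25, the chemokine gene ccl35.1 by 4.42 ± 0.36, the lysosomal protease gene ctss2.1 by 2.86 ± 0.20 (7.92 ± 0.983 to 57.2 ± 17.2 CPM) and the scavenger receptor gene marco by 2.45 ± 0.25. The inflammation and wound response list did not pass at this dose (6 of 34 risen and 6 fallen, 8 and 6 adjusted over the list alone; median 0.15, camera adjusted p = 0.44). In the neutrophil and macrophage list 13 of 31 genes rose and 4 fell (17 and 6 adjusted over the list alone; median 0.42, camera adjusted p = 0.0017, but adjusted p = 0.65 with an estimated correlation), and the call was lost without control replicate 3. Selenoprotein genes were mostly lower, with 14 of 26 fallen and 2 risen (17 and 2 adjusted over the list alone; median -0.56, camera adjusted p = 2e-04, but adjusted p = 0.65 with an estimated correlation). The largest of these falls was selenow1, from 261 ± 101 to 33.2 ± 5.83 CPM (-2.98 ± 0.25), and the call of the list was lost with control replicate 3 as the only control (median -0.18).

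Pancreas, liver and muscle genes were lower at 30 µg/L, while the intestine list (3 of 12 fallen and 2 risen, with the same counts adjusted over the list alone; median -0.43, camera adjusted p = 0.43) and the hair cell list (4 of 17 fallen and 1 risen, 4 and 2 adjusted over the list alone; median -0.33, camera adjusted p = 0.057) did not pass. Exocrine pancreas genes had 10 of 14 members fallen and 1 risen (11 and 2 adjusted over the list alone; median -1.43, camera adjusted p = 3.5e-07, but adjusted p = 0.27 with an estimated correlation), with prss59.2 at -3.44 ± 0.28 and ctrb1 at -2.64 ± 0.23. Liver genes had 27 of 51 members fallen and 6 risen (29 and 6 adjusted over the list alone; median -0.58, camera adjusted p = 5.4e-06, but adjusted p = 0.67 with an estimated correlation). Here fabp10a was at -2.82 ± 0.24 and rbp2b at -2.02 ± 0.16. The liver median was 0.084 with control replicate 3 as the only control. Skeletal muscle genes had 19 of 53 members fallen and 7 risen (23 and 7 adjusted over the list alone; median -0.35, camera adjusted p = 0.0048, but adjusted p = 0.65 with an estimated correlation). myhb was at -2.04 ± 0.13 and tnni2a.1 at -2.87 ± 0.25, and this call too was lost with control replicate 3 as the only control. Some of the largest falls at 30 µg/L were in genes back near the control level at 50 µg/L, among them the cytochrome P450 gene cyp2p9 (4.16 ± 0.409, 0.116 ± 0.0219 and 5.04 ± 0.157 CPM at 0, 30 and 50 µg/L) and the class I gene mhc1uba (3.31 ± 2.34, 0.0345 ± 0.0305 and 3.70 ± 0.496 CPM).

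In all, 2665 genes were higher and 3438 lower at 30 µg/L. Of the tested genes 37.5% did not overlap between the groups, against 10% by chance per gene. The compared groups alone gave 981 and 1333, and leaving out single libraries gave totals from 3630 to 12259, the highest without control replicate 3 (5882 higher and 6377 lower).

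**Figure D3:**
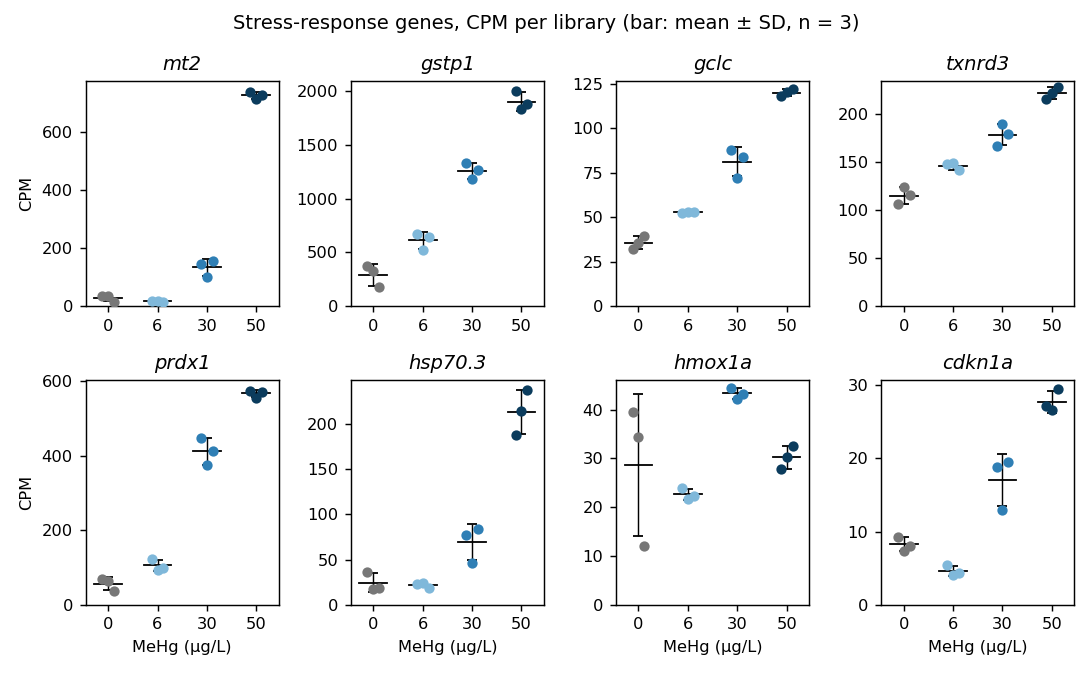
CPM of 8 stress-response genes against the MeHg concentration, with 1 point per library and bars at the mean ± SD of 3. The level of mt2 was 727 ± 12.6 CPM at 50 µg/L against 27.8 ± 10.4 CPM in controls, while hmox1a did not pass the test at any dose.

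At 50 µg/L the photoreceptor list had its lowest median and mt2 its highest level. opn1mw1 stood at 0.344 ± 0.0489 CPM against 305 ± 47.9 CPM in controls (-9.76 ± 0.40, adjusted p = 1.2e-08), and opn1sw1 changed by -8.72 ± 0.34. The cone transducin gamma gene gngt2b stood at 0.455 ± 0.0818 CPM (-8.44 ± 0.31) and gnat2 at 2.88 ± 0.338 CPM (-5.98 ± 0.20). Of the 39 photoreceptor genes 35 fell and 0 rose (35 and 0 adjusted over the list alone), with a median of -4.11 (camera adjusted p = 8.9e-93, and adjusted p = 0.0032 with an estimated correlation). The median was -3.80 without control replicate 3 and -4.48 with it as the only control. opn1mw1 and its near copy opn1mw2 (-6.20 ± 0.69) share sequence, so their separate values are uncertain. Lists of other parts of the eye did not pass at 50 µg/L. The lens list had 6 genes risen and 5 fallen of 41 (6 and 4 adjusted over the list alone; median 0.29, camera adjusted p = 0.11), and it was higher past the test without control replicate 3 (median 0.49) and with the length correction (0.43). At 6 µg/L it had 4 genes risen and 0 fallen, with the same counts adjusted over the list alone, and passed as higher (median 0.35, camera adjusted p = 0.0038, but adjusted p = 0.64 with an estimated correlation). That median was 0.42 without control replicate 3 and 0.025 with that library as the only control. The retinal pigment epithelium and Müller glia list had 4 risen and 3 fallen of 16 (4 and 3 adjusted over the list alone; median 0.07, camera adjusted p = 0.41), although its retinoid carrier genes rlbp1a and rbp3 fell by 2.02 ± 0.14 and 2.62 ± 0.20.

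mt2 rose by 4.71 ± 0.28 (adjusted p = 2.6e-07) to 727 ± 12.6 CPM, and the zinc exporter gene slc30a1a by 1.27 ± 0.12, while the second metallothionein gene mtbl fell by 1.08 ± 0.23. In the metallothionein and zinc transport list 3 of 6 genes rose and 2 fell (4 and 2 adjusted over the list alone; median 0.63, camera adjusted p = 0.019, but adjusted p = 0.17 with an estimated correlation). In the list of glutathione and Nrf2 targets 22 of 33 genes rose and 2 fell (25 and 2 adjusted over the list alone; median 0.95, camera adjusted p = 1.8e-18, but adjusted p = 0.13 with an estimated correlation). prdx1 rose by 3.32 ± 0.21, gsr by 2.84 ± 0.12, gstp1 by 2.71 ± 0.22, the autophagy receptor gene sqstm1 by 2.01 ± 0.16, gclc by 1.74 ± 0.11 and txnrd3 by 0.95 ± 0.09. Of 26 heat shock genes 17 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.70, camera adjusted p = 2.1e-10, but adjusted p = 0.13 with an estimated correlation). hsp70.3 and hspa8b were each at 3.13 (SE 0.29 and 0.26), hsp90aa1.2 at 2.47 ± 0.15 and hspa4a at 2.03 ± 0.17. Proteasome genes had 16 of 49 members risen and 0 fallen (15 and 0 adjusted over the list alone; median 0.33, camera adjusted p = 3.7e-05, but adjusted p = 0.71 with an estimated correlation), and psmb5 and psmd3 rose by 1.26 ± 0.13 and 1.65 ± 0.20. The proteasome median was 0.11 without control replicate 3 and 0.88 with that library as the only control. At this dose cdkn1a rose by 1.75 ± 0.17. hmox1a was at 0.08 ± 0.30 (adjusted p = 0.85), which was -0.29 and past the test without control replicate 3, and 1.33 with that library as the only control.

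Cell cycle genes were higher again: 37 of 50 rose and 0 fell (40 and 0 adjusted over the list alone; median 0.88, camera adjusted p = 2.1e-21, but adjusted p = 0.092 with an estimated correlation). Here top2a rose by 1.36 ± 0.09, the ribonucleotide reductase gene rrm1 by 1.38 ± 0.11 and the spindle checkpoint gene bub1bb by 1.26 ± 0.11. Neutrophil and macrophage genes had 17 of 31 risen and 2 fallen (19 and 2 adjusted over the list alone; median 0.69, camera adjusted p = 4.4e-07, but adjusted p = 0.20 with an estimated correlation). Among them were ctss2.1 (3.25 ± 0.20), marco (2.44 ± 0.25) and the perforin-like gene mpeg1.2 (1.12 ± 0.11). Inflammation genes had 15 of 34 risen and 5 fallen (16 and 5 adjusted over the list alone; median 0.63, camera adjusted p = 0.0045, but adjusted p = 0.39 with an estimated correlation). irf1b, an interferon-regulated transcription factor gene, rose by 1.71 ± 0.24, the collagenase gene mmp13a by 2.11 ± 0.20 at its higher-expressed copy, and mmp9 by 1.07 ± 0.24 (adjusted p = 0.0047). The ferritin-like genes fthl29 and fthl31 rose by 4.83 ± 0.72 and 3.73 ± 0.30. The maternal and yolk list had 4 of 5 genes risen and 0 fallen (4 and 0 adjusted over the list alone; median 1.92, camera adjusted p = 0.0077, but adjusted p = 0.25 with an estimated correlation). The vitellogenin gene vtg7 was at 2.63 ± 0.44 and the germ cell helicase gene ddx4 at 1.92 ± 0.27. That call was lost without the expression filter.

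Muscle, neuron and pancreas genes were lower. Of 53 muscle genes 30 fell and 3 rose (35 and 3 adjusted over the list alone; median -0.50, camera adjusted p = 1.3e-05, but adjusted p = 0.22 with an estimated correlation), with myhb at -2.64 ± 0.14 and tnni2a.1 at -3.59 ± 0.27. The muscle median was -0.69 without control replicate 3 and -0.14 with that library as the only control. Of 41 neuron genes 17 fell and 1 rose (17 and 1 adjusted over the list alone; camera adjusted p = 0.0013, but adjusted p = 0.75 with an estimated correlation). The neuronal differentiation gene neurod1 was at -1.32 ± 0.09, the complexin gene cplx2 at -1.40 ± 0.11, the synaptic gene snap25a at -0.93 ± 0.09 and the glutamate transporter gene slc17a7a at -2.89 ± 0.30. The neuron median was -0.33 with all controls, -0.06 without control replicate 3, where the call was lost, and -0.96 with that library as the only control. Exocrine pancreas genes had 10 of 14 members fallen and 1 risen (10 and 2 adjusted over the list alone; median -2.26, camera adjusted p = 6.4e-07, but adjusted p = 0.15 with an estimated correlation), with prss1 at -2.41 ± 0.18. The intestine list did not pass at this dose (1 of 12 risen and 2 fallen, with the same counts adjusted over the list alone; median -0.37, camera adjusted p = 0.79), and its median was 0.08 without control replicate 3. The largest fitted fall was in ggact.3, a gamma-glutamylamine cyclotransferase gene with no count in the 3 libraries at 50 µg/L, which was at least 121-fold lower than in controls when 3 counts over the group are taken as the floor.

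In all, 3492 genes were higher and 4332 lower at 50 µg/L. Of the tested genes 44.2% did not overlap between the groups, against 10% by chance per gene. The compared groups alone gave 1910 and 2503, and leaving out single libraries gave totals from 5771 to 12455, the highest without control replicate 3 (6101 higher and 6354 lower).

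**Figure D4:**
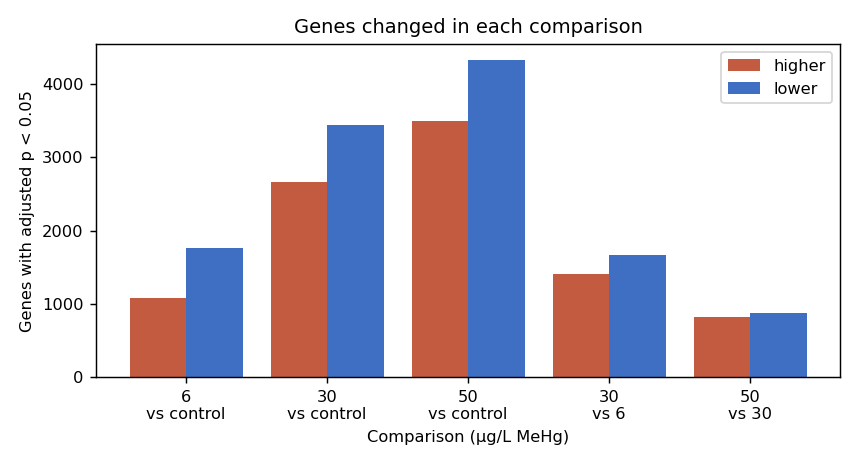
Number of genes past an adjusted p of 0.05 in each comparison, with bars for higher and lower genes. The counts were 1086 and 1760 at 6 µg/L, 2665 and 3438 at 30 µg/L and 3492 and 4332 at 50 µg/L.

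Between 6 and 30 µg/L, where no control library entered the difference, mt2 and thiol and proliferation genes rose and photoreceptor genes fell further. mt2 rose by 3.05 ± 0.26 (adjusted p = 2.3e-05), prdx1 by 1.97 ± 0.20, gsr by 1.38 ± 0.11, gstp1 by 1.04 ± 0.21, gclc by 0.62 ± 0.10 and hsp70.3 by 1.65 ± 0.27. txnrd3 (0.29 ± 0.09, adjusted p = 0.056), hmox1a (0.94 ± 0.30) and mmp9 (-0.67 ± 0.24) did not pass, though all 3 did when only the compared groups were fitted. Of the glutathione and Nrf2 targets 19 of 33 rose and 0 fell (25 and 0 adjusted over the list alone; median 0.70, camera adjusted p = 3.3e-15, but adjusted p = 0.27 with an estimated correlation). Of the cell cycle genes 33 of 50 rose and 0 fell (45 and 0 adjusted over the list alone; median 0.60, camera adjusted p = 3.8e-25, but adjusted p = 0.11 with an estimated correlation), with rrm2 at 1.85 ± 0.14 and the replication licensing gene cdc6 at 1.05 ± 0.11. The inhibitor gene cdkn1a rose 3.73-fold, from 4.61 ± 0.702 to 17.1 ± 3.58 CPM. Of the photoreceptor genes 18 of 39 fell and 0 rose (24 and 0 adjusted over the list alone; median -0.73, camera adjusted p = 9.9e-10, but adjusted p = 0.36 with an estimated correlation), with opn1sw1 at -1.45 ± 0.24. The heat shock list had 8 of 26 genes risen and 3 fallen (the same counts adjusted over the list alone; median 0.25, camera adjusted p = 0.0054, but adjusted p = 0.50 with an estimated correlation). Inflammation genes were lower than at 6 µg/L, with 11 of 34 fallen and 2 risen (14 and 2 adjusted over the list alone; median -0.27, camera adjusted p = 0.0039, but adjusted p = 0.49 with an estimated correlation). Among the falls were ptgs2b (-1.51 ± 0.23) and the chemokine genes cxcl8a (-2.06 ± 0.41) and cxcl19 (-2.38 ± 0.47). The pancreas and intestine lists were higher at 30 than at 6 µg/L, with 5 of 14 and 3 of 12 genes risen and none fallen (6 and 4 adjusted over the list alone). Their medians were 0.63 and 0.59 (camera adjusted p = 0.0019 and 0.0033, but adjusted p = 0.47 and 0.17 with an estimated correlation), and among the rises were fabp6 (2.82 ± 0.51) and the elastase gene ela2l (3.46 ± 0.54). The list calls of pancreas, intestine and inflammation were lost when only genes with a mean FPKM of at least 2 were tested.

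Between 30 and 50 µg/L, again without control libraries in the difference, the loss of cone transcripts and the rise of mt2 and of heat shock genes went on. opn1mw1 changed by -4.99 ± 0.40, gngt2b by -4.21 ± 0.32 and opn1sw1 by -3.83 ± 0.30. In the list 26 of 39 photoreceptor genes fell and 0 rose (29 and 1 adjusted over the list alone; median -1.49, camera adjusted p = 3.4e-40, and adjusted p = 0.042 with an estimated correlation). mt2 rose by 2.44 ± 0.25 (adjusted p = 0.00011), slc30a1a by 0.91 ± 0.12, gclc by 0.57 ± 0.10, gsr by 0.60 ± 0.11, hsp70.3 by 1.62 ± 0.27, cdkn1a by 0.70 ± 0.16 and mmp9 by 0.93 ± 0.24. In the metallothionein and zinc transport list 2 of 6 genes rose and 1 fell (3 and 1 adjusted over the list alone; median 0.30, camera adjusted p = 0.0088, but adjusted p = 0.22 with an estimated correlation). By contrast prdx1 (0.46 ± 0.19), gstp1 (0.60 ± 0.21), txnrd3 (0.31 ± 0.09) and hmox1a (-0.52 ± 0.30) did not pass, though these 4 did when only the compared groups were fitted. The call of mmp9 was lost without any of the 6 compared libraries and that of cdkn1a without 3 of them. Heat shock genes had 13 of 26 risen and 0 fallen (17 and 1 adjusted over the list alone; median 0.47, camera adjusted p = 1.3e-12, but adjusted p = 0.080 with an estimated correlation), with hsp90aa1.2 at 1.22 ± 0.14 and hsp90aa1.1 at 1.25 ± 0.17. Glutathione and Nrf2 targets had 10 of 33 risen and 0 fallen (17 and 1 adjusted over the list alone; median 0.45, camera adjusted p = 3.7e-06, but adjusted p = 0.50 with an estimated correlation). Neuron genes had 4 of 41 fallen and 0 risen (5 and 1 adjusted over the list alone; median -0.29, camera adjusted p = 0.0045, but adjusted p = 0.74 with an estimated correlation), with cplx2 at -0.92 ± 0.11. In all, 1413 genes were higher and 1673 lower at 30 than at 6 µg/L, and 828 and 880 at 50 than at 30 µg/L. Of the tested genes 46.5% and 43.3% did not overlap between the groups. These shares exceeded the 37.5% at 30 µg/L against control, where more genes were called, so the share did not follow the number of calls. Leaving out single libraries gave 820 to 3531 higher and 828 to 3623 lower genes in the first of these comparisons and 418 to 2507 and 434 to 2438 in the second, with the highest counts without control replicate 3. With library totals as the only scaling the counts at 30 against 6 µg/L were 995 and 2870, so the balance of rises and falls there depended on the scaling. Fitted on the compared groups alone they were 3377 and 3366, and those at 50 against 30 µg/L were 2989 and 2891.

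A linear slope on the concentration passed the test in 5934 genes, with 2637 slopes upward and 3297 downward. With library totals as the only scaling these numbers were 1869 and 4062. A slope can also pass where expression does not change steadily from dose to dose, and this was not tested. Steep rises per µg/L among genes with a named product were those of fthl29 (log2 slope 0.11 ± 0.02), mt2 (0.10 ± 0.01), fthl31 (0.08 ± 0.01) and the ubiquitin-like interferon response gene isg15 (0.07 ± 0.01). The steepest falls were in opn1mw1 (-0.16 ± 0.02), opn1sw1 (-0.16 ± 0.02) and gngt2b (-0.14 ± 0.02). A call in the same direction at all 3 doses was made for 541 higher and 953 lower genes. Leaving out single libraries moved this from 203 and 524 (without MeHg6 replicate 2) to 3850 and 3625 (without control replicate 3). Ranked by the weakest of their 3 p-values, photoreceptor genes came first, led by gnat2, gnb3b, prph2a, arr3b, gngt2b and grk1b. Independent lists of these sizes would share 25.7 higher and 66.7 lower genes, and simulated unchanged groups with shared controls shared 8.4 and 3.2. The simulated controls were redrawn gene by gene and lack the joint shift of control replicate 3. The simulation therefore does not show what the real shared controls alone would give. Across genes, which are not independent replicates, the fold changes at 6 and 30, 30 and 50, and 6 and 50 µg/L correlated with r = 0.53, 0.70 and 0.57, against 0.79, 0.79 and 0.78 for simulated unchanged groups. Their covariances were 0.221, 0.412 and 0.284 against 0.0911, 0.0915 and 0.0911 simulated. Part of these overlaps may come from the shared controls, which are too few to be split. Fitted on the compared groups alone, the count at all 3 doses was 41 higher and 258 lower, and with control replicate 3 as the only control it was 1378 and 1476.

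**Figure D5:**
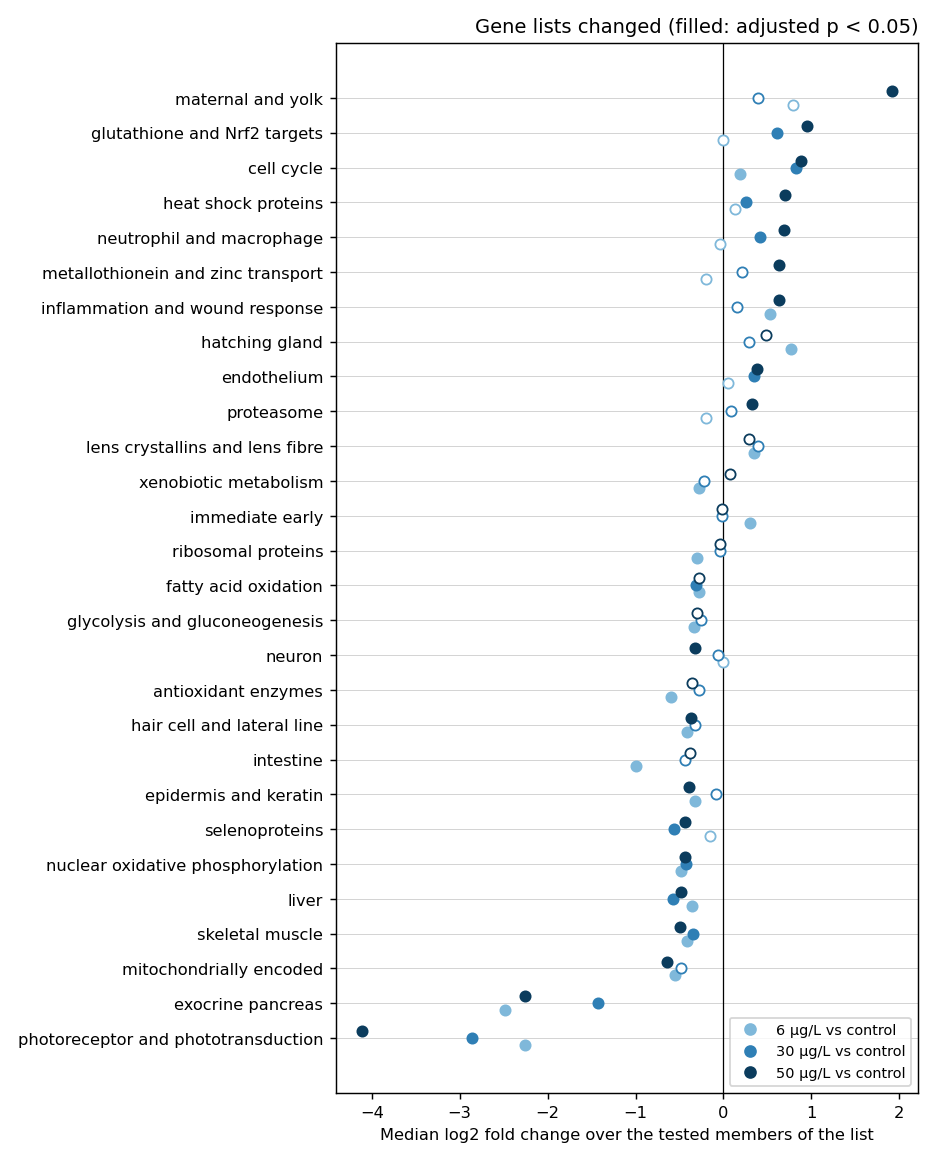
Median log2 fold change against control of gene lists that passed the camera test at 1 dose or more, without 1 list that is not shown, with filled points for an adjusted p under 0.05. Photoreceptor genes lie farthest to the left at 30 and 50 µg/L, with medians of -2.86 and -4.11, and exocrine pancreas genes at 6 µg/L, with a median of -2.48.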

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

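The tests chosen only after seeing the data were those with DESeq2, library totals only, the length correction, control replicate 3 as the only control and limma on log2(FPKM + 1). Over all alternatives, 13095 values of named genes kept their side of the threshold, 184 passed it newly, 556 lost it and 8 reversed. A change of sign was counted as a reversal only where the main or the alternative result passed. The 13095 values may therefore include changes of sign in genes that passed in neither. For gene lists 1900 values kept their direction and their call, 191 lost the call and 13 reversed. Only lists past the main test were followed here, so none could pass newly. Many of the named genes were likewise chosen for large changes or small p-values in these data. Among single alternatives, losses were most frequent for genes when only the compared groups were fitted (101) and for lists with an estimated correlation (74). The causes were not tested, except that stricter thresholds leave fewer calls by construction. Fewer libraries did not always leave fewer genes called. At 6 µg/L the total was 2846 with all libraries and 11190 without control replicate 3. The photoreceptor list stayed lower and past its test at each dose against control in every alternative run, and at 30 against 6 µg/L it lost the call only with an estimated correlation. Depth limits what low genes can show, as 3 counts stand for 0.135 to 0.192 CPM in a single library.

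An absolute log2 fold change of at least 1 left these numbers of higher and lower genes: 196 and 640 at 6 µg/L, 636 and 1012 at 30 µg/L, 985 and 1529 at 50 µg/L, 479 and 455 at 30 against 6 µg/L, 299 and 367 at 50 against 30 µg/L, 775 and 1227 in the dose trend and 45 and 271 at all 3 doses. An adjusted p under 0.01 left 294 and 737 at 6 µg/L, 1221 and 1768 at 30 µg/L, 2038 and 2657 at 50 µg/L, 638 and 698 at 30 against 6 µg/L, 343 and 363 at 50 against 30 µg/L, 1417 and 1838 in the dose trend and 128 and 399 at all 3 doses. Fitting the compared groups only gave 124 and 423 at 6 µg/L, 981 and 1333 at 30 µg/L, 1910 and 2503 at 50 µg/L, 3377 and 3366 at 30 against 6 µg/L, 2989 and 2891 at 50 against 30 µg/L and 41 and 258 at all 3 doses. With control replicate 3 as the only control, 2420 genes were higher at 6 µg/L, 3712 and 3658 higher and lower at 30 against 6 µg/L, 2477 and 2692 at 50 against 30 µg/L, and 1378 and 1476 at all 3 doses. Genes higher at 6 µg/L numbered 1729 with limma on log2(FPKM + 0.1) and 1789 with limma on log2(FPKM + 1), and genes lower at 30 against 6 µg/L numbered 2885, 2919 and, with library totals only, 2870. The correlations across genes of the fold changes at 6 and 30, 30 and 50, and 6 and 50 µg/L were 0.585, 0.747 and 0.592 with limma on log2(FPKM + 0.1), 0.650, 0.816 and 0.633 with limma on log2(FPKM + 1) and 0.646, 0.813 and 0.631 with quantile normalization. They were 0.475, 0.568 and 0.506 without a filter, 0.631, 0.802 and 0.620 at a mean FPKM of at least 2 and 0.612, 0.748 and 0.644 with control replicate 3 as the only control. Lists changed numbered 3, 2 and 1 at 6, 30 and 50 µg/L, 0 at 30 against 6 µg/L and 1 at 50 against 30 µg/L with an estimated correlation, and 10, 23, 26, 15 and 15 with fry, which does not compare a list with other genes.

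Leaving out each library in turn gave these ranges: 400 to 5664 higher and 828 to 5526 lower at 6 µg/L, 1530 to 5882 higher and 2100 to 6377 lower at 30 µg/L, 2563 to 6101 higher and 3038 to 6354 lower at 50 µg/L, 820 to 3531 higher and 828 to 3623 lower at 30 against 6 µg/L, 418 to 2507 higher and 434 to 2438 lower at 50 against 30 µg/L, 1951 to 3053 higher and 2387 to 3673 lower in the dose trend, and 203 to 3850 higher and 524 to 3625 lower at all 3 doses. The correlations ranged from 0.486 to 0.706, from 0.675 to 0.779 and from 0.543 to 0.691, and the lists changed from 17 to 22, from 12 to 17 and from 19 to 24 at 6, 30 and 50 µg/L and from 12 to 18 and from 13 to 16 between neighbouring doses. Each highest number of genes came without control replicate 3.

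With control replicate 3 as the only control, some log2 values of named genes reversed by the rule above. At 6 µg/L these were hspb1 (0.066), vtg7 (1.71), rps27.1 (0.36) and hmox1a (0.92). They were mt-nd4l (0.056) and mt-nd4 (0.12) at 30 µg/L and rps27.2 (0.34) at 50 µg/L. List medians that reversed there were, at 6 µg/L, antioxidant enzymes (0.090), liver (0.28), epidermis (0.070), glycolysis (0.12), ribosomal proteins (0.36), mitochondrially encoded (0.050) and nuclear oxidative phosphorylation (0.047). The others were liver (0.084) and nuclear oxidative phosphorylation (0.096) at 30 µg/L, and liver (0.16), epidermis (0.0096) and nuclear oxidative phosphorylation (0.086) at 50 µg/L. The median of the mitochondrially encoded list at 6 µg/L was 0 with quantile normalization. At 50 µg/L hmox1a was at -0.29 without control replicate 3, and ranged from there to 0.41 over the libraries left out. The cause was not tested.

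Whether the replicate numbers pair the samples stays open. Over 18 pairs of libraries with the same number, the correlation of their deviations from the group means ran from -0.26 to 0.35. Of these pairs 8 were over 0.1, and 6 of 12 libraries correlated best with their own number. Among pairs with different numbers, control replicate 3 was at 0.31 with MeHg6 replicate 2 and at -0.39 with MeHg6 replicate 1. A fit with the number as a block gave 1275 and 1738 at 6 µg/L, 3018 and 3385 at 30 µg/L, 3786 and 4212 at 50 µg/L, 1459 and 1598 at 30 against 6 µg/L, 809 and 831 at 50 against 30 µg/L, 2628 and 2978 in the dose trend and 702 and 943 at all 3 doses, and moved none of these numbers by over 1.5 times.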

Other observations

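Of the tests below, those of an exchanged library, a later stage, the loss of whole eyes, the control libraries with length, a developmental delay and counts near the floor were chosen only after the result was seen.

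Single cartilage genes were lower. The cartilage matrix gene matn1 stood at 542 ± 71.5 CPM in controls and at 206 ± 29.4, 162 ± 9.77 and 84.8 ± 6.31 CPM at 6, 30 and 50 µg/L (n = 3, adjusted p = 7.8e-08 at 50 µg/L), and the hypertrophic cartilage collagen gene col10a1a fell by 1.19 ± 0.11 at 50 µg/L. The cartilage and bone list as a whole did not pass there, with 8 of 30 genes lower and 3 higher (the same counts adjusted over the list alone; median -0.06, camera adjusted p = 0.18). It passed as lower with the length correction (median -0.18). Its median was 0.0042 without control replicate 3 and -0.23 with that library as the only control. In the endothelium list 10 of 25 genes rose and 2 fell at 50 µg/L (13 and 3 adjusted over the list alone; median 0.38, camera adjusted p = 0.0071, but adjusted p = 0.26 with an estimated correlation). The scavenger receptor genes stab2 and stab1 of venous and lymphatic endothelium rose by 1.89 ± 0.14 and 0.91 ± 0.12, and the vascular transcription factor gene fli1a by 0.91 ± 0.15.

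The liver glucokinase gene gck fell at each dose, by 2.73 ± 0.27, 2.92 ± 0.27 and 3.95 ± 0.30 on the log2 scale. Antioxidant enzyme genes outside the Nrf2 list were lower at 6 µg/L, with 8 of 18 fallen and 1 risen (13 and 3 adjusted over the list alone; median -0.60, camera adjusted p = 0.0024, but adjusted p = 0.63 with an estimated correlation), among them the catalase gene cat (-0.64 ± 0.09) and the superoxide dismutase gene sod1 (-0.66 ± 0.15). The list median was 0.090 with control replicate 3 as the only control. In epidermis 15 of 31 genes fell and 2 rose at 50 µg/L (17 and 2 adjusted over the list alone; median -0.39, camera adjusted p = 0.0039, but adjusted p = 0.74 with an estimated correlation), and the keratin gene krt17 went from 344 ± 59.5 to 122 ± 6.59 CPM. That list's median was 0.0096 with control replicate 3 as the only control.

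Control replicate 3 differed at least 2-fold from the mean of the other controls in 3337 genes. A trend with transcript length does not account for all of this, as 66.9% of these genes still differed at least 2-fold after a length correction. An exchange with a library of the 6 µg/L group is argued against by its photoreceptor list, which lay 2.2 log2 units above the highest library of that group. A later developmental stage of these embryos may contribute and stays open: 4 of 5 stage lists lay on that side of both other controls (hatching gland and yolk lower, photoreceptor and intestine higher), while exocrine pancreas lay on the other side. A sample from outside the series and a different clutch were not tested.

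Photoreceptor genes fell at each dose, and the loss of whole eyes is argued against by the lens list, whose median at 50 µg/L was 0.29 where the photoreceptor median was -4.11. The choice of control libraries and the length trend are argued against as well, since the weakest photoreceptor median at 50 µg/L over a length correction, the fit without control replicate 3 and that library as the only control was -3.80. A general developmental delay may contribute and cannot be told apart from an effect on the photoreceptors themselves, because at 50 µg/L 3 of 5 stage lists moved that way past the camera test (pancreas lower, yolk and cell cycle higher, but adjusted p = 0.15, 0.25 and 0.092 with an estimated correlation). The yolk call came from the maternal and yolk list, with 5 genes tested, and was lost without the expression filter. The intestine and hatching gland lists did not pass. The hatching gland median was 0.49, with 0.31 without control replicate 3 and 2.17 with that library as the only control. At 6 µg/L 4 of the 5 moved that way (pancreas and intestine lower, adjusted p = 0.011 and 0.022 with an estimated correlation, and hatching gland and cell cycle higher, but adjusted p = 0.63 and 0.66 with it and lost without control replicate 3), and at 30 µg/L 2 did (pancreas lower and cell cycle higher, adjusted p = 0.27 and 0.047 with it). An effect of the exposure on photoreceptors is thus a hypothesis that these libraries leave open.

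A set of 82 genes changed at least 4-fold in one direction from 6 to 30 µg/L and back from 30 to 50 µg/L, among them cyp2p9 and mhc1uba. Over the set as a whole, counts near the floor cannot be told apart from a real switch. The median over these genes of the highest group mean was 2.72 CPM. The genes were chosen for their swings, so this value decides nothing. Single members differed: actc1a lay above the floor throughout, at 6.53, 133 and 6.68 CPM at 6, 30 and 50 µg/L. By contrast si:ch211-147g22.4 was at 2.27, 0 and 6.36 CPM. Different parents between the groups are a candidate explanation, as 28% of these genes had another of the set within 500 kb. Over 1000 random sets matched on expression the mean was 7.4% and the highest 25.6%. Another 80 genes changed the same way in both steps, chosen by the weaker rule of at least 4-fold over the steps together. Their share was 17.5%, within its random range of up to 22.5% but above its random mean of 7.2%. Those genes thus also lay together more often than the average random set. Tandem gene families and overlapping genes also place such genes side by side, and the parents are not given in the labels, so this stays a hypothesis.

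Other splits of the libraries were fitted in the same way. For the 6 libraries of a comparison there are 10 splits, too few for a share under 0.05. At 6 µg/L 2 splits gave at least the real 2846 genes, the highest other being 6348, from MeHg6 replicate 1 with control replicates 1 and 2 against the rest. That split called far more genes than the real one, which points to a structure of the samples. At 30 and 50 µg/L 1 split, the real one, gave the 6103 and 7824 genes, and the highest other gave 0. At 30 against 6 µg/L and 50 against 30 µg/L the real split gave 3086 and 1708 genes, and the highest other 0. For lists, the real and highest other numbers were 19 and 22 at 6 µg/L (2 splits as high), 12 and 18 at 30 µg/L (9 splits), 20 and 20 at 50 µg/L (2 splits), 15 and 20 at 30 against 6 µg/L (4 splits) and 15 and 16 at 50 against 30 µg/L (2 splits). For the dose trend 1 of 50 draws, the real one, gave 5934 genes and the highest other 8. For genes called at all 3 doses 1 of 50 gave 1494 and the highest other 113. The draws shuffled single libraries and so broke up the groups, whose own libraries were alike. They show that the libraries differed by group. They cannot tell an effect of dose from another difference between the groups, as whole groups were not exchanged.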
